A study of Mus musculus with 6 samples.

How the data were processed

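Gene expression was measured in lumbar dorsal root ganglia (DRG) and lumbar spinal cord (SC) of male C57BL/6J mice aged 3 months, with 3 arrays per tissue. Each array carried biotin-labelled material from a pool of 4 mice, and the labels describe the 3 pools of a tissue as independent. The arrays were 3' expression arrays with 45101 probe sets, 64 of them controls. Signals were computed with MAS5, per the submitters' processing notes, which give no version.

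The deposited values were linear ratios, not MAS5 signals as had been assumed when the tests were chosen. The steps behind them are not given in the sources used here and were read from the values. The 6 ratios of a probe set had a median of 1 in 91.8% of probe sets, within a tolerance of 1e-05. In 8.21% of probe sets, all of low signal, the median was under 1 and the values lay on a regular grid, and 100% of these values fell on whole steps within 0.001 of a step. The lowest value was 0.01, at which 65 values stood. The deposited ratio was therefore taken as an array signal divided by a factor for its array and by the probe set's median over the 6 arrays. Because of the second division, ratios carry no level and cannot be set against a background.

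Signals were recovered from the ratios with the fact that MAS5 writes signals in steps of 0.1. For each probe set, the smallest multiplier that put all 6 values on whole steps was taken, with chance matches limited to 0.1 expected per probe set. This gave a signal for 45098 of the 45101 probe sets, and the other 3 were left out of the tests. On simulated probe sets, 98.5% of signals were recovered exactly, 1.44% were off by a whole factor common to the 6 arrays and 0.0155% were wrong. A common factor changes a level but hardly a difference between tissues. A value at the floor of 0.01 is an upper bound. After recovery, the mean signal with 2% trimmed at each end lay between 247.4 and 247.6 on the 6 arrays, as MAS5 scaling leaves it. The authors' further array factors were 84.9, 89.5 and 84.5 for DRG and 110.5, 111.9 and 112.6 for SC, close to proportional to the array medians of the recovered signal, which were 82.9, 87.5 and 82.6 in DRG and 108.3, 109.3 and 110 in SC. The comparisons kept the deposited array scaling. The signals before that scaling were run as an alternative chosen after the data were seen.

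Probe sets were named with the platform annotation supplied with the series, matched by Entrez identifier to RefSeq genes of mouse assembly GRCm38.p6, which changed no symbol. A single gene was named for 34945 probe sets, several genes for 932 and none for 9160, beside the 64 controls. Probe sets with several genes were not used. Each of the 18193 genes was represented by its probe set with the highest mean log2 value over the 6 arrays. No genome build is named by the files, and no coordinates are given. Some genes of the lists described next are not reported here.

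The difference DRG minus SC was tested on log2(signal + 16) with limma 3.58.1 in R 4.3.3, with lmFit and eBayes using an intensity trend, two-sided, with Benjamini-Hochberg adjustment over 18193 genes and a threshold of 0.05. A second count required a log2 difference of at least 1. The pseudocount of 16 makes log2 differences of dim genes smaller than those of the signals. With 3 arrays per tissue, the number of arrays limits the precision. Recovery and drawing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

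The tests, the settings to vary, 31 gene lists and the rule for named genes were fixed before the data were examined. The lists cover cell types of both tissues, cell types that dissection can bring along, gene families and disease genes, and 495 of their 576 entries were measured. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in one direction. In the text, a list's p-value is camera's adjusted p at the preset correlation unless stated otherwise. A call means an adjusted p under 0.05. The named genes were the 8 with the largest difference in each direction among called genes whose arrays did not overlap between tissues, leaving out clone and model names. Added to these were up to 3 called members of each list with the largest difference and up to 2 of the opposite direction, for a list without a call its brightest member, and Actb. A further list held 39 genes not expected in either tissue. The 95th percentile of the signals of its 53 probe sets, between 153 and 237 on the 6 arrays, served as a level for genes not expected. A gene at or under this level on all 3 arrays of a tissue has its fold given as a lower bound, the mean of the brighter tissue against the higher of this level and its own signal, with means on the log2 scale. No fold is given where the brighter tissue is not above the level either, or where no bound above 1 can be had, and a gene's place in the rule above then rests partly on signals under the level. The median of a list was also computed with such genes at their bounds, or at 0 without one, an addition made after the data were seen.

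Tested on simulated data for the comparison of DRG against SC, with 200 of 18193 genes changed, the fit recovered 80% of changes of 1 and 100% of changes of 2 on the log2 scale, and 5.26% of its calls were false. In the data a far larger share of genes was called, 43.0%, so these rates need not hold there. Alternatives were other pseudocounts, other scalings, a filter on low signals, no trend, other ways to pick probe sets, each probe set on its own, the replicate number as a block, the deposited ratio itself, and leaving out each array.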

Results

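The data were 6 arrays of adult mouse lumbar tissue, 3 of dorsal root ganglia, which hold the cell bodies of sensory neurons, and 3 of spinal cord. Each array measured a pool of 4 mice, and 18193 genes were compared. Arrays of one tissue resembled each other more than arrays of different tissues. Over all genes, the Pearson correlation of log2 signals was 0.974 to 0.977 within DRG, 0.973 to 0.976 within SC and 0.887 to 0.892 between tissues. The first principal component held 76.1% of the variance and separated the tissues.

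The tissues differed in a large part of the transcriptome. Genes of nociceptors, Schwann cells, and matrix and fibroblasts were higher in DRG as lists, and genes of astrocytes, oligodendrocytes and inhibitory neurons were higher in SC. In all, 7819 genes (43.0%) passed limma's test, 5956 higher in DRG and 1863 higher in SC, and 8873 genes had an unadjusted p under 0.05. Differences of at least 2-fold were found for 2995 genes, 2113 higher in DRG and 882 higher in SC. The 3 arrays of one tissue lay apart from the 3 of the other for 51.7% of genes, where chance gives 10%. Among called genes, 888 stood above the level of genes not expected only in DRG, 502 only in SC and 834 in neither tissue.

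The excess of calls toward DRG changed with the array scaling. The share of called genes that were higher in DRG was 76.2% on the deposited scaling, 56.1% after quantile normalization and 49.1% with signals before the authors' array scaling, and at 2-fold it was 70.6%, 54.6% and 44.7%. The median gene differed by 0.18 on the log2 scale, 0.04 and −0.10 in the same order. The median of genes above the median signal differed by 0.39, 0.04 and 0.03. Differences of these sizes have no settled direction, and some larger ones lack it too. Genes of ATP synthase, a family picked after the results were seen, had medians of 0.50, −0.07 and 0.13 in the same order. Of the 7819 called genes, 5714 kept call and direction after quantile normalization and 5451 before the array scaling, and 166 and 7 were called in the opposite direction. Of the 2995 genes with a 2-fold difference, 2983 kept their call and direction after quantile normalization and 2928 before the array scaling, and 0 reversed. Staying at 2-fold was not required for this. The array factors differ by less than 2-fold between tissues, so leaving them out could not reverse such genes. Before the array scaling, the 2-fold calls went from 2113 to 1174 toward DRG and from 882 to 1450 toward SC.

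The genes with the largest differences toward DRG were known genes of peripheral sensory neurons. Pirt, a membrane protein of these neurons, had a signal of 7365 ± 44.8 (SD, n = 3) in DRG and 40.4 ± 6.12 in SC, at least 43.9-fold (limma adjusted p = 3.66e-10). P2rx3, an ATP-gated channel, was at least 22.6-fold higher, Avil, an actin-binding protein, at least 37.9-fold, Acpp, an ectophosphatase, at least 15.4-fold, and Tmem45b at least 19.8-fold. The voltage-gated sodium channel genes Scn11a and Scn10a were at least 31.0-fold and 9.46-fold higher. Fxyd2, a subunit of the sodium pump, was at least 25.3-fold higher on a probe set that can match several transcripts. With such probe sets left out, its log2 difference was 0.01 (limma adjusted p = 0.972, the highest over its alternatives, from 9.93e-12).

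Toward SC the leading genes were glial and central neuronal. In DRG, none of them was above the level of genes not expected, so their lead rests partly on signals under it. Gfap, the astrocyte intermediate filament, had a signal of 6568 ± 602 (SD, n = 3) in SC and 90.4 ± 26.4 in DRG, at least 35.9-fold (limma adjusted p = 1.09e-08). The astrocyte glutamate transporter Slc1a2 was at least 35.4-fold higher in SC and the neuronal chloride transporter Slc12a5 at least 26.2-fold. Olig1, a transcription factor of the oligodendrocyte lineage, was at least 12.2-fold higher and Ermn, an oligodendrocyte cytoskeletal protein, at least 9.54-fold. Lamp5 was at least 12.8-fold higher and Itih3 at least 9.76-fold. Mog, a myelin protein of oligodendrocytes, stood at the lowest deposited value on all 3 DRG arrays and was at least 6.83-fold higher in SC.

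**Figure D1:**
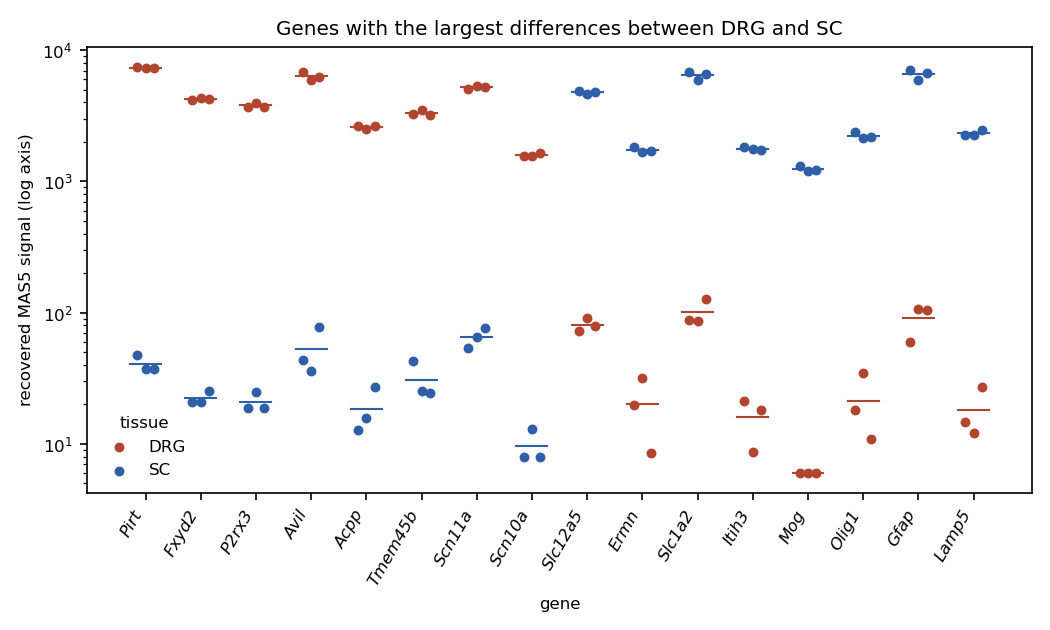
Recovered MAS5 signal on a log axis for the 8 genes with the largest differences toward each tissue. Points are single arrays, 3 DRG in red and 3 SC in blue, and lines are tissue means. The DRG points of Mog are upper bounds. Pirt averaged 7365 in DRG and 40.4 in SC, and Gfap 90.4 in DRG and 6568 in SC.

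Genes of nociceptors, the sensory neurons that respond to noxious stimuli, were higher in DRG throughout. All 17 measured members passed the test, among them P2rx3, Scn11a and Scn10a. Their median log2 difference was 3.80 (camera adjusted p = 3.46e-11, or adjusted p = 0.0232 with an estimated correlation). All 11 transcription factors of sensory neurons were also higher, with a median of 2.70 (camera adjusted p = 9.97e-07). Isl1 was at least 13.1-fold higher, Pou4f1 at least 6.70-fold and Runx1 at least 3.80-fold. The call of the transcription factors was lost with an estimated correlation (adjusted p = 0.0706). Of 15 genes of mechanoreceptors and proprioceptors, 9 were higher in DRG and 1 in SC, with a median of 0.92 (camera adjusted p = 0.0253, or adjusted p = 0.189 with an estimated correlation). The split was 9 against 3 after quantile normalization and 8 against 5 before the array scaling, with medians of 0.59 and 0.56. The ion channel genes Piezo2 and Asic3 were at least 10.9-fold and 8.05-fold higher in DRG and Tafa4 at least 4.57-fold, while Necab2 was higher in SC at −0.69. The list was not called among genes above the median signal (camera adjusted p = 0.503) or with the mean of a gene's probe sets (0.281).

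Most genes of spinal neurons were higher in SC. Of 12 genes of inhibitory neurons, 11 were higher in SC, with a median log2 difference of −2.87 (camera adjusted p = 4.78e-12). Slc6a5, the neuronal glycine transporter, was at least 9.14-fold higher in SC, Gad1, which makes GABA, at least 10.3-fold, and the glycine receptor gene Glra1 at least 9.08-fold. Of 12 genes of cholinergic motor neurons, 8 were higher in SC, with a median of −0.88 (camera adjusted p = 9.97e-07, or adjusted p = 0.0706 with an estimated correlation). Slc18a3, the vesicular acetylcholine transporter, was at least 3.29-fold higher in SC, Chodl at least 2.85-fold and Uts2 at least 1.14-fold. Chat, Lhx3, Lhx4 and Esrrb were not called. Chat differed by −0.25 (limma adjusted p = 0.362) and was not above the level of genes not expected in either tissue.

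Genes expressed by neurons of both tissues were higher in DRG in 13 of 18 cases and higher in SC in 2, with a median log2 difference of 0.86 (camera adjusted p = 0.000922, or adjusted p = 0.201 with an estimated correlation). Prph, an intermediate filament of peripheral neurons, differed by 4.17, Sncg by 3.94 and the neuronal tubulin Tubb3 by 2.35. Map2, a protein of dendrites, and the intermediate filament Ina were higher in SC, at −1.35 and −1.19. With quantile normalization the split was 11 against 5 and the median 0.30, and before the authors' array scaling 11 against 5 and 0.49. Among genes above the median signal, the list was not called (camera adjusted p = 0.0624).

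Lists of glial genes differed in opposite directions. All 16 Schwann cell genes were higher in DRG, with a median log2 difference of 1.70 (camera adjusted p = 9.08e-07), among them the neurotrophin receptor Ngfr, at least 32.9-fold higher, Cdh1, at least 11.7-fold, and Scn7a, with a log2 difference of 4.18. Ngfr and Scn7a are also in the lists of neurotrophic signalling and sodium channels, so their differences need not be glial. Of the 16 genes, 2 were not above the level of genes not expected in either tissue. Of 19 oligodendrocyte genes, 17 were higher in SC, or 18 adjusted over the list alone, with a median of −3.22 (camera adjusted p = 6.66e-20, or adjusted p = 0.00792 with an estimated correlation). Olig1, Mog and Ermn are members. Of 20 astrocyte genes, 19 were higher in SC, with a median of −3.29 (camera adjusted p = 1.68e-22, or adjusted p = 0.00792 with an estimated correlation). Agt, which encodes angiotensinogen, was at least 6.81-fold higher in SC. The exception was S100b, at 0.32 (limma adjusted p = 0.00699), which reversed to −0.24 after quantile normalization (0.0213), was not called before the array scaling at −0.05, and was not called with the logarithm of the deposited ratio (limma adjusted p = 0.0535). Over its alternatives the adjusted p ran from 0.000942 to 0.618. Of 14 genes of myelin in both systems, 11 were higher in SC and 2 in DRG, with a median of −1.42 (camera adjusted p = 4.87e-08). The gap junction gene Gjb1 was at least 3.70-fold higher in SC and the myelin glycoprotein Mag differed by −3.57, while the tetraspanin Cd9 was higher in DRG at 3.24 and the receptor Erbb3 at 0.78.

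Most of the glutamate and GABA-A receptor genes that were called were higher in SC. Of 22 glutamate receptor genes, 12 were higher in SC, or 13 adjusted over the list alone, and 3 were higher in DRG, with a median log2 difference of −0.66 (camera adjusted p = 1.26e-05). The split was 3 against 13 after quantile normalization and 2 against 15 before the array scaling, with medians of −0.75 and −0.99. Grm5 and Grm3 were at least 3.45-fold and 1.61-fold higher in SC. The kainate receptor subunit Grik1 was at least 14.9-fold higher in DRG, and Grm7 was higher at 1.25, or 0.19 as the mean of its probe sets (limma adjusted p = 0.406, the highest over its alternatives, from 1.57e-06). Of 13 GABA-A receptor genes, 7 were higher in SC and 0 in DRG, with a median of −0.36 (camera adjusted p = 6.93e-05). The median was −0.71 after quantile normalization and −0.72 before the array scaling. Gabrb1 and Gabra5 were at least 3.35-fold and 3.02-fold higher in SC, and Gabra4 was called higher in SC without a bound on its fold.

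Sodium and TRP channel genes split between the tissues. Of 11 sodium channel genes, 5 were higher in DRG and 4 in SC. Their median log2 difference was −0.09 and their mean 1.72 (camera adjusted p = 0.736, while fry called the list higher in DRG with adjusted p = 1.76e-06). The split was 5 against 6 on both other scalings, with medians of −0.65 after quantile normalization and −0.46 before the array scaling. Scn9a, a channel of peripheral neurons, was at least 11.5-fold higher in DRG beside Scn11a and Scn10a, while Scn2a was higher in SC at −1.87. Scn3a was called higher in SC but was not above the level of genes not expected in either tissue. Of 19 TRP channel genes, 7 were higher in DRG and 4 in SC, with a median of 0.13 that turned to −0.12 before the array scaling (camera adjusted p = 0.954). Trpv1, the capsaicin receptor, was at least 9.13-fold higher in DRG, Trpa1, a receptor for irritants, at least 5.25-fold and Trpv2 at least 4.25-fold. Trpc7 and Trpc5 were called higher in SC without a bound on their fold, but the calls depended on single arrays. Leaving out DRG replicate 2, DRG replicate 3 or SC replicate 1 ended the call of Trpc7 (limma adjusted p = 0.0717, 0.0707 and 0.0775), as did the logarithm of the deposited ratio (0.0747), and leaving out SC replicate 1 ended that of Trpc5 (0.0579). Their lowest values over the alternatives were 0.00058 and 0.00225.

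Neuropeptide genes also split. Of 22, 8 were higher in DRG and 12 in SC, or 13 adjusted over the list alone, with a median log2 difference of −0.96 (camera adjusted p = 0.0128, or adjusted p = 0.274 with an estimated correlation). Nmb, which encodes neuromedin B, was at least 18.2-fold higher in DRG. Tac2 was at least 4.02-fold higher in SC and Cck, which encodes cholecystokinin, at least 2.39-fold. Among genes above the median signal, the list's median was 1.67, and camera's adjusted p was 0.646. It was 0.0906 after quantile normalization, with a split of 7 against 12, and 0.196 before the array scaling, with 7 against 14. Of 20 genes of neurotrophic signalling, 10 were higher in DRG and 4 in SC, with a median of 0.62 (camera adjusted p = 0.148). The median was 0.41 after quantile normalization and 0.29 before the array scaling. Ret, the receptor of the GDNF family, differed by 3.25, and Osmr, the oncostatin M receptor, was at least 4.64-fold higher in DRG. Sort1 and Ntrk2 were higher in SC at −1.39 and −0.65. Of the 8 probe sets of Ntrk2, 3 were called higher in SC and 1 higher in DRG. This list was called after quantile normalization (camera adjusted p = 0.0375) and before the array scaling (0.0223).

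Hox genes, which pattern the body axis, were mostly higher in SC. Of 33, 18 were higher in SC, or 19 adjusted over the list alone, and 1 in DRG, with a median log2 difference of −0.58 (camera adjusted p = 1.13e-08, or adjusted p = 0.0706 with an estimated correlation). The split was 1 against 19 after quantile normalization and 1 against 24 before the array scaling, with medians of −0.78 and −0.89. Hoxc8 and Hoxc10 were at −2.12 and −1.97. Hoxd1 was higher in DRG, with signals of 451 ± 41.7 and 32.2 ± 3.52 (SD, n = 3 each), at least 2.68-fold. By paralogue number, a grouping chosen after the values were seen, calls toward SC fell on 5 of 10 genes of paralogue groups 1 to 4, 9 of 13 of groups 5 to 9 and 4 of 10 of groups 10 to 13. Among genes above the level of genes not expected in at least 1 tissue, they fell on 4 of 7, 8 of 10 and 4 of 4.

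Genes mutated in inherited neuropathy were higher in DRG in 23 of 33 cases and in SC in 2, with a median log2 difference of 0.72 (camera adjusted p = 0.00028). Besides Scn9a, the heat shock gene Hspb8 was higher in DRG at 2.44, while Gjb1 and Litaf were higher in SC, the latter at −0.55. Genes of motor neuron disease and hereditary spastic paraplegia were higher in DRG in 15 of 21 cases and in SC in 0, with a median of 0.64 (camera adjusted p = 0.000323, or adjusted p = 0.119 with an estimated correlation). L1cam, a cell adhesion molecule, differed by 2.41, Reep1 by 1.75 and Atl1 by 1.45, the last pair shaping the endoplasmic reticulum. Before the array scaling, the splits were 17 against 6 and 11 against 2, with medians of 0.35 and 0.27, and after quantile normalization 17 against 7 and 9 against 3, with medians of 0.25 and 0.32.

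**Figure D2:**
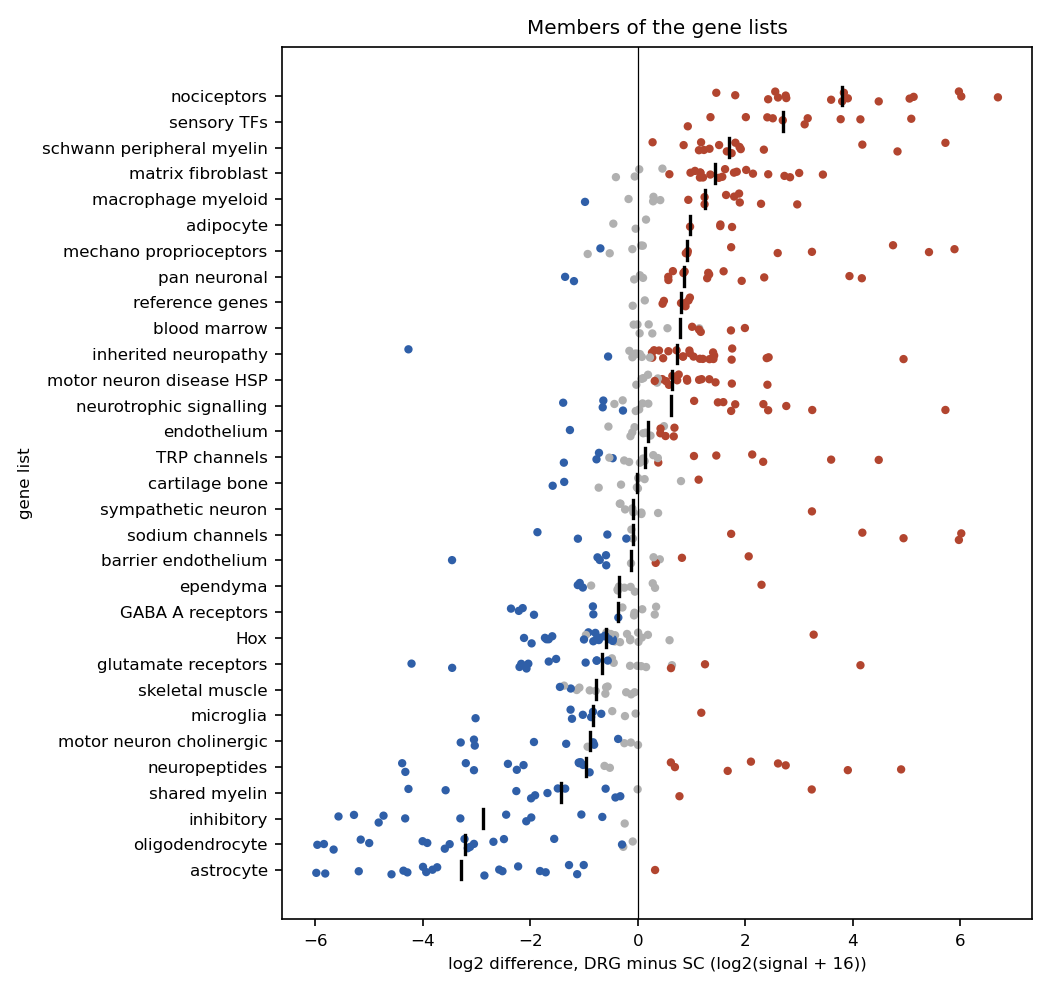
Log2 difference, DRG minus SC, on log2(signal + 16), for each measured member of the 31 gene lists, sorted by list median. Red points were called higher in DRG, blue higher in SC and grey points were not called, black bars are medians, and vertical scatter within a list has no meaning. Medians ran from −3.29 for astrocyte genes to 3.80 for nociceptor genes.

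Genes of matrix and fibroblasts were higher in DRG, while the lists of adipocytes and of cartilage and bone were not called. Of 24 genes of matrix and fibroblasts, 20 were higher in DRG, with a median log2 difference of 1.43 (camera adjusted p = 4.22e-07), and adjusted over the list alone 1 was higher in SC. The proteoglycan gene Dcn differed by 3.45 and the collagen gene Col3a1 by 3.00, and Lum was at least 4.19-fold higher in DRG. Of 7 adipocyte genes, 4 were higher in DRG, with a median of 0.97, which was 0.88 after quantile normalization and 0.63 before the array scaling (camera adjusted p = 0.387). Car3 was at 1.54 and Fabp4 at least 1.20-fold higher, while Adipoq was not above the level of genes not expected in either tissue. Of 10 cartilage and bone genes, 1 was higher in DRG and 2 in SC, with a median of −0.01 that was 0.02 after quantile normalization (camera adjusted p = 0.108). Before the array scaling the split was 1 against 3 and the median −0.27. Comp was called higher in DRG, and Acan, a proteoglycan also found around central neurons, higher in SC, both without a bound on the fold, and Col11a2 was at least 1.10-fold higher in SC.

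Vascular genes differed little as a group. Of 14 endothelial genes, 5 were higher in DRG and 1 in SC, with a median log2 difference of 0.19. Set against other genes, camera's direction was toward SC (camera adjusted p = 0.954). Flt1, a receptor for vascular growth factor, was higher in SC at −1.26. Cdh5 was at least 1.11-fold higher in DRG and Esam was higher at 0.67, and neither was called before the array scaling (limma adjusted p = 0.124 and 0.144), where the split was 0 against 2 and the median −0.14. The call of Esam also ended after quantile normalization (limma adjusted p = 0.0692), where the split was 1 against 1 and the median 0.08. That of Cdh5 ended with the mean of its probe sets (limma adjusted p = 0.0657). Of 11 genes of barrier endothelium, 3 were higher in DRG and 5 in SC, with a median of −0.12, which was −0.59 after quantile normalization and −0.49 before the array scaling (camera adjusted p = 0.135). Slco1c1, a thyroid hormone transporter, was at least 2.07-fold higher in SC. The efflux pump Abcg2 was higher in DRG at 2.06, and Spock2 at 0.82, or −0.01 without a call as the mean of its probe sets. The split was 2 against 7 after quantile normalization and 2 against 6 before the array scaling. The list was called after quantile normalization (camera adjusted p = 0.0266).

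Most called microglia genes were higher in SC and most called genes of other myeloid cells higher in DRG. However, 5 of 11 and 8 of 14 genes of these lists were not above the level of genes not expected in either tissue. With genes at their bounds, both list medians were 0. Of 11 microglia genes, 7 were higher in SC, or 8 adjusted over the list alone, and 1 was higher in DRG, with a median log2 difference of −0.83 (camera adjusted p = 0.00022). The purine receptor P2ry12 was at least 1.51-fold higher in SC and the transcription factor Sall1 at least 1.29-fold, Gpr34 was not above the level of genes not expected in either tissue, and Olfml3 was higher in DRG at 1.18. Of 14 genes of macrophages and other myeloid cells, 9 were higher in DRG and 1 in SC, with a median of 1.24 (camera adjusted p = 0.0199, or adjusted p = 0.251 with an estimated correlation). The class II antigen genes H2-Aa and H2-Ab1 were at least 6.58-fold and 2.82-fold higher, and Cd74 differed by 1.90. Clec10a was called higher in SC but was not above the level in either tissue. Gpr34 was not called with the logarithm of the deposited ratio (limma adjusted p = 0.0954), and the myeloid list was not called without probe sets that can match several transcripts (camera adjusted p = 0.0745).

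Lists of other cell types mostly showed few calls. Of 9 genes of sympathetic neurons, Th alone was called, at least 5.95-fold higher in DRG, and it is also a gene of sensory neurons with low mechanical thresholds. The list's median was −0.08 and its mean 0.30 (camera adjusted p = 0.536). Before the array scaling its median was −0.32, with 1 gene higher in DRG and 2 in SC. Of 13 ependymal genes, 3 were higher in SC, or 2 adjusted over the list alone, and 1 in DRG, with a median of −0.35 (camera adjusted p = 0.0291, or adjusted p = 0.137 with an estimated correlation). The list was not called after quantile normalization, before the array scaling or without DRG replicate 1 (camera adjusted p = 0.215, 0.125 and 0.0646). Its medians there were −0.35, −0.57 and −0.22. Ccdc153 and Enkur were called higher in SC, neither above the level of genes not expected in either tissue. Enkur lost its call in 10 of 16 alternatives, among them leaving out any array but SC replicate 2 (limma adjusted p over its alternatives 0.00248 to 0.147). Rarres2 was at least 2.04-fold higher in DRG, with a log2 difference of 2.30, or −0.70 without probe sets that can match several transcripts (limma adjusted p = 0.0567, the highest over its alternatives, from 3.29e-05). Of 12 blood and marrow genes, 5 were higher in DRG, with a median of 0.78 (camera adjusted p = 0.512), among them the neutrophil genes Camp and Elane and the red cell gene Alas2, the last pair not above the level in either tissue. The split was 3 against 0 after quantile normalization and 2 against 0 before the array scaling, with medians of 0.63 and 0.45. The list's median signal was 138, 112 and 105 on the DRG arrays and 94.4, 67.1 and 137 on the SC arrays. The SC arrays thus differed among themselves, with SC replicate 3 near the highest DRG array. The call of Elane was lost without DRG replicate 2, without DRG replicate 3, without SC replicate 1 and without SC replicate 2 (limma adjusted p = 0.0707, 0.0512, 0.0673 and 0.0711), and also before the array scaling (0.0829) and with the logarithm of the deposited ratio (0.0646), while its lowest value was 0.00187.

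Skeletal muscle genes varied between arrays of one tissue. The median signal of the 13 genes was 42.4, 61.4 and 202 on the DRG arrays and 49.8, 192 and 225 on the SC arrays. Between tissues, 2 were higher in SC, or 1 adjusted over the list alone, and the median log2 difference was −0.78 (camera adjusted p = 0.0051, or adjusted p = 0.454 with an estimated correlation). The list was also not called after quantile normalization (0.0505), before the array scaling (0.0653) or among genes above the median signal (0.162). Myh2, a myosin heavy chain, and Mb, which encodes myoglobin, were the called genes, neither above the level of genes not expected in either tissue. The call of Mb was lost with the mean of its probe sets (limma adjusted p = 0.124), and that of Myh2 without single arrays. Without DRG replicate 1 its adjusted p was 0.071, and without DRG replicate 2, SC replicate 2 or SC replicate 3 it was 0.0602, 0.0744 and 0.0728, with a lowest value of 0.000602 over the alternatives.

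**Figure D3:**
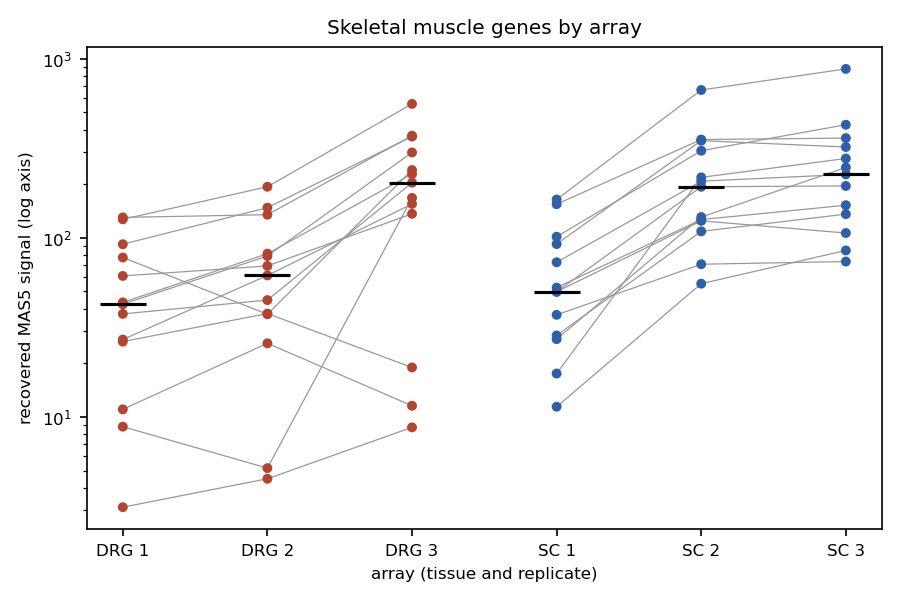
Recovered MAS5 signal on a log axis of the 13 skeletal muscle genes on each array, DRG in red and SC in blue. Grey lines join the values of one gene within a tissue, whose replicates have no order, and black bars are medians. The medians were 42.4, 61.4 and 202 in DRG and 49.8, 192 and 225 in SC.

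Genes often used as references were also higher in DRG on the deposited scaling. Of 9, 7 were higher in DRG and 0 in SC, with a median log2 difference of 0.81 (camera adjusted p = 0.0132, or adjusted p = 0.245 with an estimated correlation). Ywhaz, Rplp0 and B2m led at 0.97, 0.94 and 0.89, and B2m was not called after quantile normalization (limma adjusted p = 0.0657). Actb differed by 0.49 (limma adjusted p = 0.00152), 0.03 after quantile normalization (0.817) and 0.12 before the array scaling (0.281). The split was 4 against 1 after quantile normalization, where the list was not called (camera adjusted p = 0.295), and 5 against 1 before the array scaling, with medians of 0.28 and 0.44. Signs of RNA quality moved with the tissue too. The ratio of 3' to 5' control signals was higher on all 3 DRG arrays, at 0.816, 0.832 and 0.817 against 0.702, 0.694 and 0.678 in SC for Gapdh and 1.52, 1.73 and 1.69 against 1.43, 1.20 and 1.32 for Actb (exact permutation test, two-sided p = 0.1 for each, the smallest that 3 arrays against 3 allow).

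Over the 31 lists, 22 were called, 10 higher in DRG and 12 higher in SC. With an estimated correlation 11 were called, namely nociceptors, Schwann cells, oligodendrocytes, shared myelin, astrocytes, inhibitory neurons, glutamate receptors, GABA-A receptors, inherited neuropathy, matrix and microglia. Camera's adjusted p for these ran from 0.00792 for astrocytes and oligodendrocytes to 0.0418 for microglia, far less extreme than at the preset correlation for many of them. With genes not above the level in a tissue set at their lower bounds, or at 0 without one, list medians were 2.47 for nociceptors, 1.97 for sensory transcription factors, 1.14 for Schwann cells, −1.89 for oligodendrocytes, −2.77 for astrocytes, −1.30 for inhibitory neurons, −0.10 for cholinergic motor neurons and −0.04 for Hox genes. They were 0.46 for mechanoreceptors and proprioceptors, 0.15 for adipocytes and −0.22 for skeletal muscle. They were 0 for glutamate receptors, GABA-A receptors, neuropeptides, microglia, macrophages, sodium and TRP channels, endothelium, sympathetic neurons, ependyma, cartilage and bone, and blood and marrow. For 23 lists the counts of genes adjusted over the list alone equalled those over all genes, and the other 8 differed by 1 gene each.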

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

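The signals before the authors' array scaling and the logarithm of the deposited ratio were chosen as alternatives after the data were seen, the others before. The 109 named genes had 1819 values under alternatives. Of these, 1778 kept direction and side of the threshold, 37 kept direction but lost the call and 4 changed sign, and 93 genes were unchanged in every alternative run for them. S100b reversed to −0.24 after quantile normalization, where it was called. The other 3 changes of sign were not calls: S100b was −0.0484 before the array scaling. Leaving out the array factors, which were higher for SC, by construction moves bright genes toward SC. Spock2 was −0.00627 as the mean of its probe sets and Rarres2 −0.70 without probe sets that can match several transcripts, alternatives that by construction use other probe sets of the gene. Of 587 values of lists, 550 kept their side of the threshold, and their direction where called, 27 lost a call, 7 gained one, and 3 changed direction with a call before or after. Among lists not called, medians also changed sign, that of the TRP channels to −0.12 and that of endothelium to −0.14 before the array scaling. The neuropeptide list had a median of 1.67, without a call, among genes above the median signal, where fewer of its genes are tested, and fry, which does not compare a list with other genes, put the lists of endothelium (median 0.19) and sympathetic neurons (−0.0807) higher in DRG.

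After quantile normalization 3899 genes were higher in DRG and 3056 in SC, and 1375 at 2-fold in DRG. Before the array scaling, 3588 were higher in DRG and 3724 in SC, and at 2-fold 1174 and 1450. These shifts follow from the scalings themselves, and which scaling is right was not settled. With a pseudocount of 64, which by construction makes differences of dim genes smaller, 558 genes were 2-fold higher in SC, and 446 among genes above the median signal, where fewer genes are tested. With each of 45034 probe sets tested on its own, 14615 were called, 10206 higher in DRG and 4409 in SC, and 5967 at 2-fold, 3806 and 2161. For 305 genes, probe sets were called in both directions. Lists called were 11 with an estimated correlation, 4 higher in DRG and 7 in SC, and fry called 16 higher in DRG. Besides sodium channels, these held TRP channels, neurotrophic signalling and adipocytes, which camera did not call (fry adjusted p = 0.00101, 1.72e-05 and 0.00116). Neuropeptides and skeletal muscle, called by camera, were not called by fry (adjusted p = 0.131 and 0.311). Leaving out single arrays gave 7053 to 7776 called genes, 2960 to 3120 at 2-fold and 21 to 22 lists, with fewer samples. No detection calls were used here, and 7516 genes were not above the level of genes not expected in either tissue, which limits what can be said of them.

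With the replicate number as a block, 7712 genes were called and 22 lists. Whether the numbers pair the arrays could not be settled. Deviations of arrays of the same number correlated at 0.01, −0.01 and 0.08, the last the highest of all pairs. Not every array correlated best with its own number, and with 3 arrays per tissue these correlations can show little. The counts over other splits of the arrays were chosen after the results were seen. The real split of the 6 arrays gave 7819 genes, 2995 at 2-fold and 22 lists, and the highest of the other 9 splits 0, 0 and 15. Each of the other splits mixes both tissues unequally in each group, which puts much of the tissue difference within the groups and leaves part of it between them. Their counts therefore give no rate of calls by chance. The limma tests of those splits gave up to 347 genes at an unadjusted p under 0.05. In each case 1 of the 10 splits gave a result as large, and 10 splits are too few for a share under 0.05.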

Other observations

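The tests and genes in this part were chosen after the results were seen, except that the muscle genes outside the list were fixed before their values were examined. The 37 gene families looked at were matched by symbol, mostly by its start, so that some hold a few genes of another kind. The 36 families with measured genes were tested with camera and Benjamini-Hochberg adjustment. At the preset correlation 12 were called and with an estimated correlation 0, where the lowest adjusted p was 0.283.

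Genes with symbols of the proteasome, which degrades tagged proteins, were higher in DRG in 42 of 49 cases and in SC in 0, with a median log2 difference of 0.92 (camera adjusted p = 1.71e-08, or adjusted p = 0.363 with an estimated correlation). The split was 35 against 2 after quantile normalization and 36 against 3 before the array scaling, with medians of 0.44 and 0.55. Psmd14 had signals of 3494 ± 358 and 1398 ± 121 and Psmb3 of 1622 ± 134 and 653 ± 27.1 in DRG and SC (SD, n = 3 each). Genes of cholesterol synthesis were higher in DRG in 10 of 11 cases, with a median of 1.20 (camera adjusted p = 0.00145, or adjusted p = 0.33 with an estimated correlation), and the split was 7 against 1 on both other scalings, with medians of 0.68 after quantile normalization and 0.84 before the array scaling. Fdps differed by 1.72 and Sqle by 1.53. Annexins, calcium-dependent membrane proteins, were higher in DRG in 7 of 11 cases (camera adjusted p = 0.027, or adjusted p = 0.33 with an estimated correlation), and Anxa2 had signals of 10396 ± 282 and 609 ± 28.5 (SD, n = 3 each). Genes of respiratory complex I and its assembly were higher in DRG in 30 of 44 cases on the deposited scaling, but split 4 against 16 after quantile normalization and 9 against 8 before the array scaling.

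Genes with symbols starting in Nkx, Pax, Lhx, Dbx or Irx, mostly homeodomain genes but also others such as the transcript Lhx1os, which was among the calls, were higher in SC in 14 of 41 cases and in DRG in 1, with a median of −0.33 (camera adjusted p = 7.72e-05, or adjusted p = 0.283 with an estimated correlation), among them Nkx2-2, at least 1.40-fold higher, which the oligodendrocyte list also holds. The split was 0 against 14 after quantile normalization and 0 against 20 before the array scaling, with medians of −0.34 and −0.64. The metallothionein genes Mt1 and Mt2 were higher in SC, at −1.97 and −1.62 (limma adjusted p = 4.18e-08 and 1.11e-05). Among serotonin receptors, Htr2c was at least 5.84-fold higher in SC, and Htr3a and Htr3b, subunits of the ion channel type, were at least 4.72-fold and 1.48-fold higher in DRG. Of 9160 probe sets with no gene named, 1274 were called, 283 of them at least 2-fold higher in DRG and 300 in SC.

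The excess of calls toward DRG, 5956 against 1863 genes, ended with signals before the authors' array scaling, at 3588 against 3724, so the array scaling is a candidate cause. The 18 hybridization control probe sets, for transcripts added in fixed amounts, had a median log2 difference of 0.40 on the deposited scaling and 0.03 before it. Leaving out SC replicate 2, where they were dimmest, gave 0.22 and −0.15. The 39 genes not expected in either tissue had medians of 0.01 and −0.15, while 6 of them were called higher in DRG and 1 in SC on the deposited scaling and 3 and 2 before it. The shift in calls follows from the scaling itself, as the median of genes above the median signal went from 0.39 to 0.03. Which scaling is right stays open, since the calls of the genes not expected go with the controls and their median does not. These genes are dim, with a median probe set signal of 34.4 to 45.3 on the 6 arrays. The pseudocount makes their log2 differences smaller, so their medians cannot be set against those of the controls by size. That both sets had to move was required only after both values were seen, and on the controls alone the scaling would have been taken as the cause. The tissue difference itself, including the higher 3' to 5' ratios in DRG, also stays open, as untested.

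Skeletal muscle genes differed between arrays of one tissue, with Acta1 at 126, 192 and 558 on the DRG arrays and 163, 667 and 875 on the SC arrays, Atp2a1 at 91.8, 147 and 366 and at 154, 353 and 359, and 4 of the 13 genes not above the level of genes not expected in either tissue. The authors' array scaling is argued against as the cause, since their array factors lay at most 0.0527 on the log2 scale from the mean of their tissue while the muscle list's median deviated by up to 1.09. Other effects of single arrays, such as labelling, were not tested, because the scaling itself brings the array medians together. Of the 13 genes, 11 were highest on DRG replicate 3 within DRG and 13 lowest on SC replicate 1 within SC, and 0 of them are in another list. Muscle carried over in dissection may account for it, which predicts that muscle genes outside the list follow the same arrays. For 38 such genes, the median deviation from the tissue mean was 0.09 on DRG replicate 3 and −0.22 on SC replicate 1. The difference, 0.31 on the log2 scale, lay at percentile 100 of 10000 random lists matched on signal, whose highest value was 0.25. The shift was smaller than in the list, 32 of the 38 genes were not above the level of genes not expected in either tissue, and 19 were highest on DRG replicate 3 and 24 lowest on SC replicate 1. No biological explanation was tested, since the tissue groups do not separate these arrays.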
